A study of Homo sapiens with 4 samples.

How the data were processed

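Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 histone modifications in untreated MHCC97L cells, an established human hepatocellular carcinoma cell line. The modifications were acetylation of histone H3 at lysine 27 (H3K27ac), monomethylation at lysine 4 (H3K4me1) and trimethylation at lysine 4 (H3K4me3). Each mark had 1 library, and a further library of input chromatin completed the 4 samples. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum at 37 °C and 5% CO2. The input library was not analysed here.

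The authors deposited 1 list of peak summits per mark. Each line gives a position 1 bp wide, a peak name and a score, with no peak width and no read count. Per the submitters' processing notes, Bowtie, Picard, deepTools and MACS2 were used on the hg38 build; their versions and settings, and whether the input served as the control, are not given in the sources used here. The score deposited by the authors is a −log10 value of a p-value or q-value. The lowest score was 1.30, 1.33 and 1.31 in the H3K27ac, H3K4me1 and H3K4me3 lists. The lowest of them equals a q-value or p-value of 0.05, and which of the 2 was used is not given in the sources used here. The score depends on sequencing depth and on the level of background, so it was used to describe, rank or filter summits within a list. Medians of the H3K4me3 list, and of the H3K27ac list, were set beside each other by chromosome. Scores of different marks are not compared as signal. Each list came from 1 library and no replicates were pooled, so no test of a difference between marks was possible. The p-values given are for correlations over chromosomes.

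Summits on chromosomes 1 to 22 and X were analysed. Summits on chromosome Y and on unplaced contigs were left out: 273 for H3K27ac, 61 for H3K4me1 and 185 for H3K4me3. Gene positions came from NCBI RefSeq genes on GRCh38.p14, which uses the same chromosome coordinates as hg38. There were 19970 protein-coding genes, 18177 long noncoding RNA (lncRNA) genes and 59094 genes of all types. The gene table used here gives the start and end of each gene without strand, transcripts or exons. A promoter could therefore not be told from the other end of its gene, and the planned assignment to transcription start sites was replaced by assignment to gene boundaries. A gene counted as carrying a mark when a summit lay within 1000 bp of either boundary, and as carrying H3K4me3 with H3K27ac when both lay within 1000 bp of the same boundary. Genes with starts inside their outer limits, or whose summit lay further into the gene, are missed by this rule, and a count with summits anywhere in the gene or within 1000 bp of it was made beside it. In that whole-gene count both marks could lie at any distance from each other. Exon and intron classes, matching of random lists on CpG content, a single start site per gene and the planned motif search need transcripts or sequence and were not run.

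Summits of different marks were called co-located within 1000 bp of each other, and distal when over 2500 bp from every boundary of a gene of any type. The co-location expected by chance came from 100 circular shifts of the second list, each chromosome moved by its own random distance with a fixed seed. For gene counts and locations, 20 of these shifts were used. Shifted summits could fall anywhere along a chromosome, including stretches where no summit can be called. Distal H3K27ac summits closer than 12000 bp to each other were stitched into clusters and ranked by their number of summits, with distances to genes taken from the midpoint of the cluster. Without read signal per region these clusters are no super-enhancer calls. Distal H3K27ac summits with H3K4me1 were assigned to the protein-coding gene with the nearest boundary.

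For shares, 95% Wilson confidence intervals were computed, which cover counting error only, since summits are not replicates. The read depth of the libraries is unknown. The 26 gene lists were written before the data were examined: 21 of named genes, 4 by gene symbol pattern and 1 of lncRNA genes. Of the 412 entries named by symbol, 410 matched a gene, by symbol or by a synonym of 1 gene. Each list's number of marked genes was placed among 10000 random lists of the same size drawn from the other protein-coding genes, or lncRNA genes for the lncRNA list. The percentile describes these libraries and is not a p-value. Random lists were drawn gene by gene, while neighbouring members of a list can share a summit. The genes named in the text followed a rule also fixed before the data were examined. It took from each list the first 2 members, in the order written, with H3K4me3 and H3K27ac and the first 2 without H3K4me3, and the member with most distal sites, and named genes that share a boundary window with another protein-coding gene together with it. It added the 10 genes with the highest H3K27ac score, the 10 with the highest H3K4me3 score among those without H3K27ac, the 15 largest clusters, list genes nearest to the 50 largest clusters, the 10 genes with most distal sites and the 5 highest-scoring distal H3K4me3 summits. Some genes that this rule takes are not reported here.

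Alternatives covered boundary windows of 500 and 2500 bp, distal limits of 1000 and 5000 bp, co-location within 500 and 2000 bp, a score of at least 10, lists cut to equal length by score, merging of summits of 1 mark within 500 bp, stitching within 5000 and 20000 bp, ranking of clusters by summed score, and a limit of 100000 bp to the nearest gene. Chosen after seeing the data were summits anywhere in the gene, leaving out chromosome 13, distal H3K27ac summits without H3K4me3, and random lists matched on gene length or on chromosome. Matched lists were used for the boundary count only, so percentiles over the whole gene may depend on gene length. The functions were tested on simulated data: 1200 of 1200 genes with a planted H3K4me3 summit were recovered and 0 of 1800 without 1 were called, and 822 of 822 planted co-located summits were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.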

Results

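The series describes the chromatin state of MHCC97L hepatocellular carcinoma cells through H3K4me3, a mark of promoters, H3K4me1, a mark of enhancers and promoter flanks, and H3K27ac, a mark of active promoters and enhancers. The cells were untreated, and each mark was measured in 1 library. On chromosomes 1 to 22 and X the lists held 70028 H3K27ac summits, 86366 H3K4me1 summits and 46078 H3K4me3 summits. The median score, the authors' −log10 value for each summit, was 8.40 for H3K27ac, 4.58 for H3K4me1 and 8.23 for H3K4me3, which describes each list and is no comparison of signal between marks. A score of at least 10 was reached by 43.5% of the H3K27ac summits, 7.87% of the H3K4me1 summits and 43.2% of the H3K4me3 summits. With no replicates, the values describe these 3 libraries, and the intervals given are 95% Wilson intervals for counting error only.

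H3K4me3 summits were concentrated at the boundaries of protein-coding genes, H3K27ac summits less so, and H3K4me1 summits mostly lay inside genes. Of the H3K4me3 summits, 29.1% (28.6 to 29.5) lay within 1000 bp of a protein-coding gene boundary, against 2.79% on average when the list was shifted along the chromosomes, a 10.4-fold excess. The same share was 20.1% (19.8 to 20.4) for H3K27ac, 7.51 times its shifted value, and 3.85% (3.72 to 3.98) for H3K4me1, 1.44 times its shifted value. Inside protein-coding genes and away from their boundaries lay 57.3% of the H3K4me1 summits, against 41.9% after shifting. This location took in 42.3% of the H3K27ac summits, within the range of the shifts, and 43.8% of the H3K4me3 summits, above the highest of 20 shifts at 42.8%. Stretches where no summit can be called were not left out of the shifts, so this small H3K4me3 difference cannot be read as an excess. Intergenic sequence held 15.5% of the H3K4me3, 23.9% of the H3K27ac and 25.6% of the H3K4me1 summits, each below the lowest of 20 shifts. H3K4me3 summits at boundaries had a median score of 41.2, against 5.78 for those inside genes. With a window of 2500 bp the H3K4me1 share rose to 10.2% (8793 summits).

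H3K4me3 and H3K27ac were found together, and the strongest H3K4me3 summits seldom had H3K4me1 close by. An H3K27ac summit lay within 1000 bp of 61.5% (61.1 to 61.9) of the H3K4me3 summits, against at most 4.33% in 100 shifts. An H3K4me1 summit lay as near to 33.9% (33.5 to 34.3) of them, against at most 5.35%. Among the 9216 H3K4me3 summits with the highest scores, 90.3% (89.6 to 90.9) had H3K27ac and 4.34% (3.94 to 4.78) had H3K4me1. The latter share is near the 4.66% that shifted H3K4me1 lists gave on average for all H3K4me3 summits. Among the 9216 with the lowest scores the shares were 44.4% (43.4 to 45.4) and 51.1% (50.1 to 52.1). Around the 11609 highest-scoring H3K4me3 summits, H3K4me1 summits within 250 bp occurred at 0.193 times their genome-wide density. Their density was 1.78 times the genome-wide value between 500 and 1000 bp and 4.09 times between 1500 and 2000 bp. H3K27ac summits within 250 bp were at 41.1 times their genome-wide density.

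**Figure D1:**
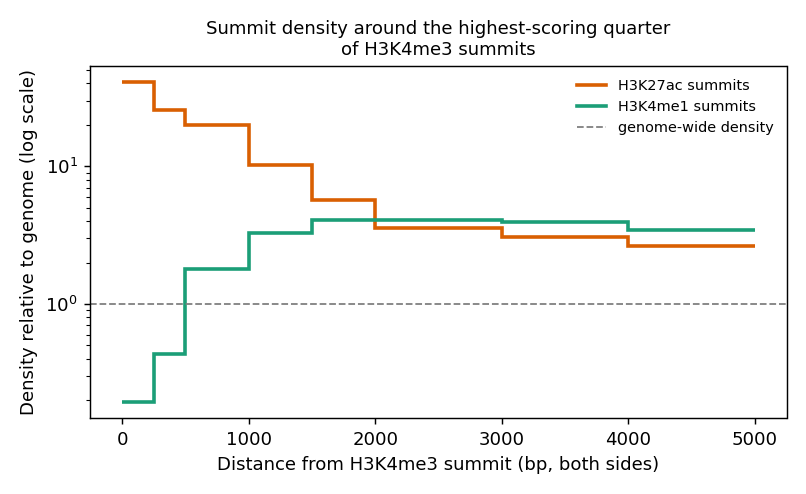
Density of H3K27ac and H3K4me1 summits, relative to their genome-wide density (y, log scale), by distance in bp from the 11609 highest-scoring H3K4me3 summits (x, both sides together). The H3K27ac line starts at 41.1 and falls with distance, while the H3K4me1 line starts at 0.193 and reaches 4.09 between 1500 and 2000 bp.

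H3K27ac summits had H3K4me1 within 1000 bp in 52.8% (52.5 to 53.2) of cases and H3K4me3 in 42.5% (42.1 to 42.9), against at most 5.00% and 3.11% in the shifts. With rising H3K27ac score the share with H3K4me3 grew from 20.8% in the 14006 lowest-scoring summits to 72.8% in the 14006 highest, while the share with H3K4me1 went from 55.9% to 44.5%. Neither mark accompanied 20.4% of the H3K27ac summits, and their median score was 5.50, against 17.99 for those with H3K4me3 alone. Of the H3K4me1 summits, 49.6% (49.28 to 49.95) had H3K27ac and 22.1% (21.8 to 22.3) had H3K4me3 within 1000 bp. A score of at least 10 in each list left 6801 H3K4me1 summits, and the share of H3K27ac summits with H3K4me1 was then 8.95%.

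**Figure D2:**
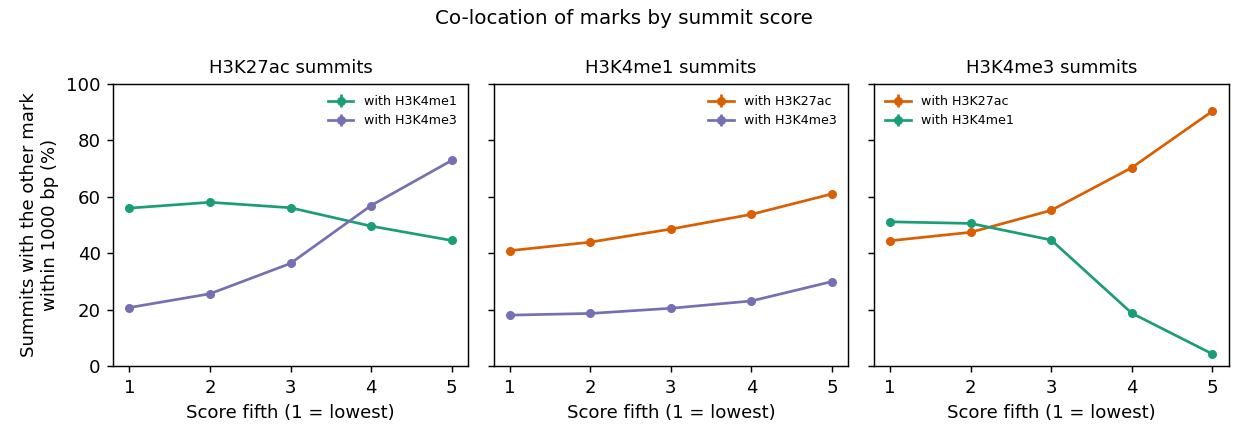
Percent of summits of each mark with a summit of another mark within 1000 bp (y) in 5 groups of equal size by the summit's own score (x, 1 is the lowest). Points carry 95% Wilson intervals, which are mostly smaller than the points; for H3K4me3 the share with H3K27ac reaches 90.3% and the share with H3K4me1 falls to 4.34%.

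Boundaries stand in for promoters here and include the other end of each gene. Of the protein-coding genes, 11340 of 19970 (56.8%, 56.1 to 57.5) carried H3K4me3 at a boundary, 10806 (54.1%, 53.4 to 54.8) carried H3K27ac and 2486 (12.4%, 11.998 to 12.91) carried H3K4me1. Shifted lists gave on average 1106 genes with H3K4me3, 1478 with H3K27ac and 1620 with H3K4me1. H3K4me3 was found at 1 boundary in 10470 genes and at both in 870. Both H3K4me3 and H3K27ac marked the same boundary in 9459 genes (47.4%, 46.7 to 48.1), against 52.95 on average and 71 at most in shifted lists. Independent lists of these lengths would give 6136 genes with both marks at any boundary, the same or not. The 1881 genes with H3K4me3 and no H3K27ac beside it had a median best H3K4me3 score of 14.0, against 57.2 for the 9459. None of the marks was found at a boundary of 7023 genes (35.2%, 34.5 to 35.8). A window of 500 bp lowered the genes with H3K4me3 and H3K27ac to 6220, and a window of 2500 bp raised them to 11135. Both marks lay anywhere in the gene, near each other or not, in 12228 genes. The genes with H3K4me1 went from 1461 at 500 bp to 4971 at 2500 bp.

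The highest H3K27ac scores at gene boundaries belonged to CAPZA2 (188), which encodes an actin capping protein subunit, SGK2 (183), a serum- and glucocorticoid-regulated kinase gene, and ZMYND8 (170), a chromatin reader gene. They were followed by CLDND2 and ETFB, which share a boundary and its score of 167, the splicing factor gene SRSF2 (164), ANKRD40 (163), WDR81 (159), the histone gene H4C15 (157) and S100A2 (156), which encodes a calcium-binding protein. SGK2, ZMYND8 and SRSF2 had no H3K4me3 summit within 1000 bp of a boundary but had 1, 9 and 1 in the gene, with best scores of 76.2, 37.1 and 115. SRSF2 shares a boundary with METTL23 and MFSD11, and ANKRD40 with ABCC3. S100A2 had a best H3K4me3 score of 6.03 and a best H3K4me1 score of 27.1. Among genes without H3K27ac at a boundary, the highest H3K4me3 scores belonged to KMT2E (115), TRPS1 (111), NRCAM (110), DRC10 (107) and ABCC2 (105), which encodes a canalicular export pump of hepatocytes. They were followed by the carbonic anhydrase gene CA12 (100.5), ARMC7 and SLC16A5 (100.4 each, at a shared boundary), SEPTIN9 (98.2) and HES1 (97.4), a Notch target gene. In these 10 genes the nearest H3K27ac summit lay between 1031 bp (TRPS1) and 2115 bp (NRCAM) from a boundary. KMT2E shares a boundary with SRPK2, DRC10 with TPCN1 and ARMC7 also with NT5C.

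Most genes of mature hepatocyte function lacked the pair of promoter marks, while part of the liver transcription factor genes carried it. Of 35 hepatocyte function genes, 7 had H3K4me3 with H3K27ac at the same boundary (interval 10.0% to 35.9%), against a median of 17 in random lists (percentile 0.045). With summits anywhere in the gene, near each other or not, the number with both marks was 10 against 22 (percentile 0.030). No random lists, here or for the lists below, were matched on CpG content, so its part in the percentiles was not tested. ALB, the gene of serum albumin, had no summit of any mark in the gene or within 1000 bp of it, and its nearest H3K4me3 summit lay 21053 bp from a boundary. APOA2, an apolipoprotein gene, had none either. FGA, a fibrinogen gene, had best scores of 14.2 for H3K4me3 and 29.5 for H3K27ac, and TF, the transferrin gene, had 85.8 and 33.6 but shares a boundary with TOPBP1. UGT2B7, which encodes a glucuronosyltransferase, had an H3K27ac score of 99.8 and most distal sites of the list, 9. H3K4me1 was found at a boundary of 12 of the 35 genes, at percentile 99.94 of random lists, and anywhere in the gene in 16, at percentile 74.2. Of 20 liver transcription factor genes, 10 had H3K4me3 with H3K27ac (interval 29.9% to 70.1%, percentile 59.4), or 16 with summits anywhere in the gene (percentile 95.7). HNF4A, which encodes a nuclear receptor of the hepatocyte lineage, had an H3K4me3 score of 71.9 and an H3K27ac score of 57.6. FOXA2 had H3K4me3 inside the gene (95.1) but not within 1000 bp of a boundary, and FOXA3 had none. RXRA, a nuclear receptor gene, had 28 distal sites.

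Among 20 fetal liver and hepatic progenitor genes, 2 had H3K4me3 with H3K27ac at the same boundary (10.0%, 2.79 to 30.1, percentile 0.025), namely SOX9 and CD44. This low count rested on the boundary window, since 10 had both marks with summits anywhere in the gene (percentile 15.7) and 10 with a window of 2500 bp (percentile 30.3). AFP, the gene of alpha-fetoprotein, had an H3K27ac summit of 67.2 and a weak H3K4me3 summit of 7.29 inside the gene and none at its boundaries. GPC3, a glypican gene used as a liver cancer marker, had no H3K4me3 or H3K27ac summit, and neither had EPCAM, an epithelial adhesion gene. Of 16 epithelial genes 6 carried the pair (percentile 22.2) and of 20 mesenchymal genes 9 did (percentile 42.5). The keratin genes KRT8 and KRT18, neighbours on chromosome 12, shared a best boundary H3K4me3 score of 107, and GRHL2 had 22 distal sites. TJP1, a tight junction gene, had H3K4me3 of 80.8 inside the gene. In the mesenchymal list VIM had H3K4me3 of 11.6 at a boundary and 35.3 in the gene, ZEB1 had 53.8, and FN1, the fibronectin gene, had 69.3 with 25 distal sites. ZEB2 had 60.5 inside the gene, and TWIST1 had no summit of any mark.

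Genes of growth and of basic cell functions carried the pair of marks in high numbers. It was found in 20 of 22 proliferation genes (90.9%, 72.2 to 97.47, above all 10000 random lists), including MKI67 and the topoisomerase gene TOP2A with H3K4me3 scores of 26.9 and 93.6. MCM4 and RRM2 had no H3K4me3 within 1000 bp, with the nearest summits 1615 and 1174 bp from a boundary, and MCM4 shares a boundary with PRKDC. The pair was found in 16 of 19 cholesterol and fatty acid synthesis genes (84.2%, 62.4 to 94.5, percentile 99.94). All 19 had both marks somewhere in the gene, near each other or not. HMGCS1, an enzyme gene of cholesterol synthesis, had an H3K4me3 score of 50.3, and SQLE and FDFT1 had 103 and 55.2 inside the gene. Of 81 cytosolic ribosomal protein genes 71 had the pair (87.7%, 78.7 to 93.1), and of 76 histone genes 58 did (76.3%, 65.6 to 84.5), both above all random lists. RPL10L, a ribosomal protein copy, and the linker histone genes H1-6 and H1-7 had no H3K4me3. Of 20 core housekeeping genes 14 had the pair (70.0%, 48.1 to 85.5, percentile 97.7), with GAPDH (shared boundary with IFFO1) at 94.7 and PPIA at 97.8 for H3K4me3. ACTB and YWHAZ were missed at the boundary, with H3K4me3 of 73.0 and 93.5 inside the gene. When the whole gene was counted, 19 of the 20 had both marks, near each other or not. Chromatin modifier genes had the pair in 17 of 24 cases (70.8%, 50.8 to 85.1, percentile 98.9, or 97.41 among random lists matched on gene length). Among them were KMT2B, whose boundary is shared with IGFLR1 and ZBTB32, and KMT2C, which encode H3K4 methyltransferases. All 24 had both marks somewhere in the gene.

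For lists tied to liver cancer signalling, the count of genes with the pair depended on the window. Counts over the whole gene took both marks at any distance from each other, and their random lists were not matched on gene length. At 1000 bp all 5 of these gene lists lay within the central 95% of unmatched random lists, while YAP and TEAD target genes were at percentile 98.3 among random lists matched on gene length. At 2500 bp driver genes (21 of 24, percentile 99.94), YAP and TEAD target genes (20 of 22, percentile 99.985) and hypoxia and glycolysis genes (16 of 20, percentile 98.6) lay above it. YAP and TEAD target genes had the pair at 1000 bp in 15 of 22 cases (68.2%, 47.3 to 83.6, percentile 97.2), over the whole gene in 19 (percentile 99.3) and with a score of at least 10 in 9 (percentile 52.7), with CCN1 and CCN2 at H3K4me3 scores of 29.6 and 22.8. ANKRD1 had neither H3K4me3 nor H3K27ac, and TGFB2, with H3K4me3 of 75.9 inside the gene, had 51 distal sites. The AP-1 transcription factor genes had it in 8 of 13 cases (percentile 83.8), or 5 with a score of at least 10 (percentile 46.3), with JUN at 75.9 and JUNB (shared boundary with HOOK2) at 51.8, and MAF had no summit of any mark. Hypoxia and glycolysis genes had it in 12 of 20 (percentile 86.7) and over the whole gene in 18 (percentile 99.8), with LDHA at 82.3 and PFKP (shared boundary with PITRM1) at 42.7. Liver cancer driver genes had it in 13 of 24 (percentile 74.5) and over the whole gene in 21 (percentile 99.7). TERT, the telomerase gene, had H3K4me3 of 23.9 and H3K27ac of 10.6, and AXIN1, which shares a boundary with PDIA2, had 60.01 and 25.9. CTNNB1, the beta-catenin gene, had H3K27ac of 38.8 at a boundary, with the nearest H3K4me3 summit 1327 bp away. Wnt target genes had the pair in 5 of 15 (percentile 14.4), with a score of at least 10 in 3 (percentile 5.63), at 2500 bp in 9 (percentile 62.3) and over the whole gene in 12 (percentile 93.0), with RNF43 (shared boundary with SUPT4H1) at 82.5 and ZNRF3 at 51.8 for H3K4me3, and AXIN2 and GLUL at 101.3 and 58.6 inside the gene.

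Markers of other cell types and tissue-restricted genes rarely carried the pair. It was found in 1 of 12 stellate cell and fibroblast markers (percentile 0.30), 0 of 12 endothelial markers (percentile 0.025), 1 of 12 myeloid and Kupffer cell markers (percentile 0.32), 0 of 12 lymphocyte markers (percentile 0.020) and 1 of 14 heart and skeletal muscle genes (percentile 0.10). The 3 exceptions, RGS5, CD68 and TNNC2, share a boundary with NUF2, EIF4A1 and SNX21 in that order. COL1A1, COL1A2, CD3D, MYH6 and MYH7 had no summit of any mark in the gene. PECAM1, an endothelial adhesion gene, had H3K27ac of 43.9 at a boundary and H3K4me3 of 25.4 inside the gene. Neuron genes had the pair in 3 of 14 cases (percentile 2.85, or 2.44 among lists matched on gene length, and 2 cases at percentile 2.35 with a score of at least 10), SYP, MAP2 and TUBB3, the last named after its value was seen, and none of 16 cancer-testis genes or 390 olfactory receptor genes did. HOX genes had H3K4me3 in 20 of 39 cases (percentile 24.3) and H3K27ac in 16 (percentile 5.47). Both marked the same boundary in 9 (23.1%, 12.6 to 38.3, percentile 0.125, or 2.23 among lists matched on gene length), including HOXA10 and HOXA13. With a window of 2500 bp 20 HOX genes had the pair (percentile 28.4), and 15 had both marks anywhere in the gene (percentile 0.22). Of 28 lncRNA genes studied in liver cancer 17 had the pair (60.7%, 42.4 to 76.4, above all random lists of lncRNA genes), with NEAT1 at an H3K27ac score of 159 and MALAT1 at 101.5. HULC had no summit of any mark, and HOTAIR had weak summits inside the gene, at 6.45 for H3K4me3 and 6.72 for H3K27ac.

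**Figure D3:**
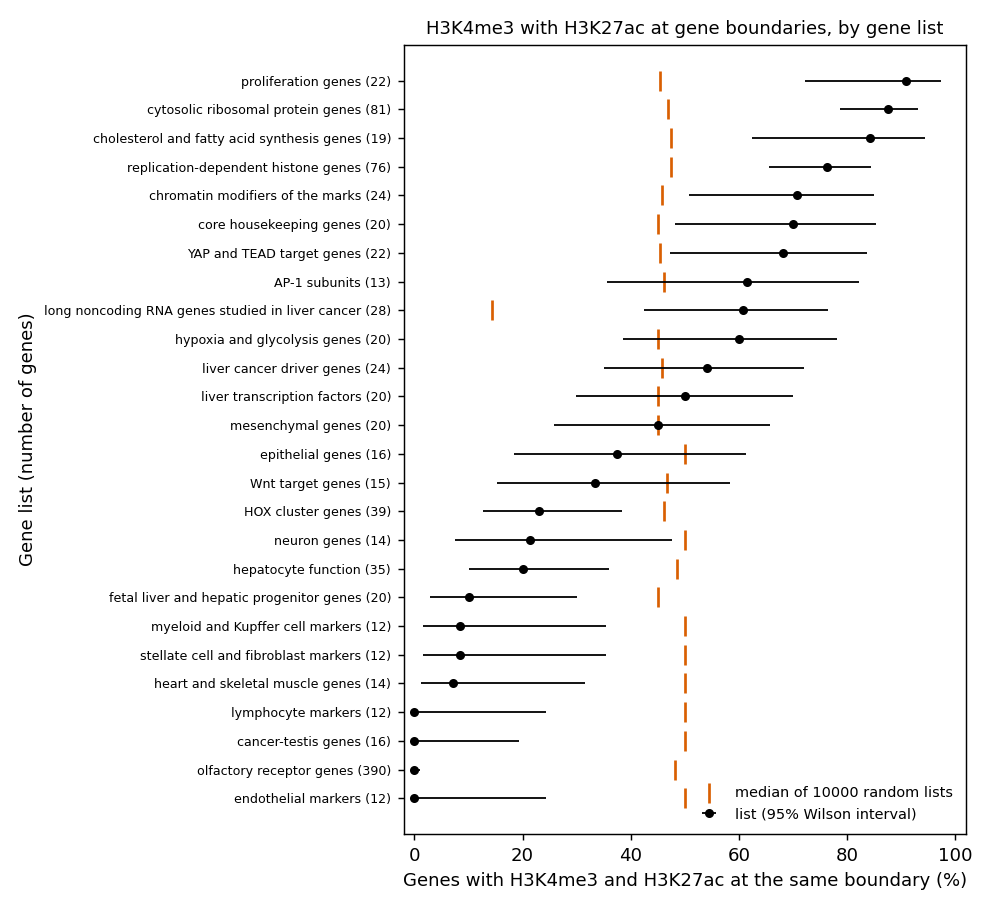
Percent of genes in each list with H3K4me3 and H3K27ac within 1000 bp of the same gene boundary (x), with 95% Wilson intervals; the bar marks the median of 10000 random lists of the same size, and the number of genes is in brackets. Proliferation genes are at 90.9% and the upper interval bound of hepatocyte function genes is 35.9%.

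Away from gene boundaries, most H3K27ac summits had H3K4me1 within 1000 bp, the pairing that textbooks use for active enhancers, though fewer did within 500 bp. Of 44001 H3K27ac summits over 2500 bp from every gene boundary, inside genes or between them, 29011 (65.9%, 65.5 to 66.4) had an H3K4me1 summit within 1000 bp, against at most 5.00% in 100 shifts. For all distal H3K27ac summits the share was 48.3% with co-location within 500 bp and 77.2% within 2000 bp. At 1000 bp it was 66.5% for the distal H3K27ac summits without H3K4me3 within 1000 bp. H3K4me3 lay within 1000 bp of 29.0% (28.6 to 29.4) of the distal H3K27ac summits. Of 68009 distal H3K4me1 summits, 34263 (50.4%, 50.004 to 50.76) had no H3K27ac within 1000 bp, the pattern described for primed enhancers. Their median score was 4.43, against 5.03 for those with H3K27ac. The share without H3K27ac was 67.0% with co-location within 500 bp and 36.3% within 2000 bp. With a score of at least 10 in every list, 2212 of 15613 distal H3K27ac summits (14.2%) had H3K4me1. Starts inside genes count as distal here, since the gene table gives outer limits only.

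With no limit on distance, MYC, an oncogene of cell growth, was the gene with most distal sites carrying both H3K27ac and H3K4me1. Of the 29011 sites 107 were nearest to MYC, against a median of 0 over all genes and 8 at the 95th percentile. Within 100000 bp MYC had 28 sites and ranked 25, and TNS3 with 44 and SLC39A11 with 43 had most. Without a limit MYC was followed by SLC39A11, a zinc transporter gene, with 83 sites, the focal adhesion gene LPP with 81 (30 within 100000 bp), RAD51B with 71 (9 within 100000 bp), the tensin gene TNS3 with 67, TBL1XR1 with 66 (16 within 100000 bp), the protein kinase C gene PRKCA with 57 (21), TGFB2 with 51 (28), NSMCE2 with 50 (39) and the polarity gene PARD3 with 49 (23). NSMCE2 shares a boundary with WASHC5. The sites nearest to SLC39A11 include a cluster that overlaps LINC00673 on chromosome 17. Among members with the most sites of their own list, HK1, the hexokinase gene, had 25, YWHAZ 22, PECAM1 20, JUN 15, RPS23 and OR13H1 12 each and KDM6A 10. At least 10 sites were nearest to 776 genes, and to 549 when the gene had to lie within 100000 bp. With a score of at least 10 in every list, 7 genes had that many.

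H3K27ac summits formed dense clusters, the largest overlapping SLX4IP and JAG1, PVT1, and LINC00824. Stitching gave 15729 clusters, of which 588 held at least 10 summits and together 19.3% of the distal H3K27ac summits. The largest, on chromosome 20 from 10536884 to 10669305, held 53 summits, 44 of them with H3K4me1, and JAG1, which it overlapped, is a Notch ligand gene. The next 2 lay on chromosome 8. From 127784905 to 127928809, 52 summits formed a cluster that overlapped the lncRNA gene PVT1, and MYC was the nearest protein-coding gene, 113906 bp from the midpoint of the cluster. From 128529627 to 128666559, 50 summits formed a cluster that overlapped the lncRNA gene LINC00824, with its midpoint 855142 bp from MYC. Clusters of 30 to 40 summits overlapped PPM1H on chromosome 12, MEGF9 on chromosome 9, TRIO on chromosome 5, LINC00673 on chromosome 17, AOPEP on chromosome 9, MMP20 on chromosome 11, SEPTIN9 on chromosome 17, MYH9 on chromosome 22, ATXN1 on chromosome 6, MAML3 on chromosome 4 and ERRFI1 on chromosome 1. HK1 and FN1 were further list genes nearest to 1 of the 50 largest clusters, with 29 summits in the cluster that overlapped HK1 and 23 in a cluster whose midpoint lay 245514 bp from FN1. The order of clusters depended on the settings: of the 15 largest, 8 overlapped the first 15 by summed score, 7 and 6 those with stitching within 5000 and 20000 bp, 5 those from lists of equal length and 3 those with a score of at least 10. At that score 3 clusters held 10 or more summits.

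**Figure D4:**
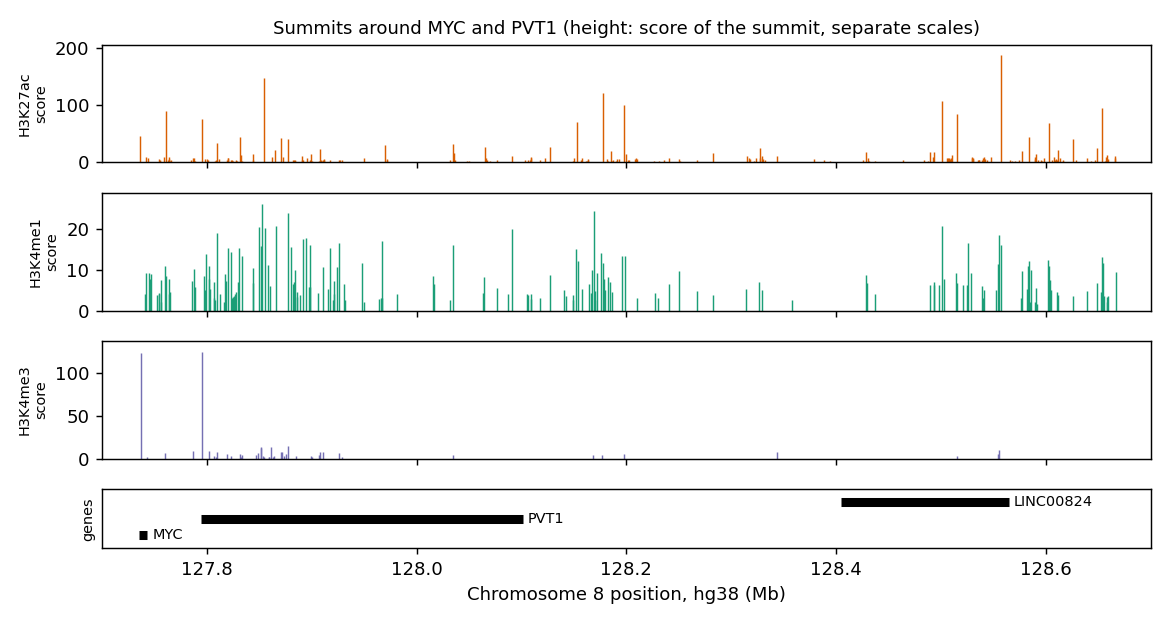
Summits of the 3 marks on chromosome 8 around MYC, PVT1 and LINC00824 (x, position in Mb, hg38), with line height giving the authors' score on a separate scale per mark (y) and bars for the 3 genes. The region holds 210 H3K27ac, 183 H3K4me1 and 46 H3K4me3 summits, and 2 H3K4me3 summits, in MYC (124) and at the left end of PVT1 (125), have the highest scores of their list there, the next being 15.1.

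H3K4me3 was also called away from gene boundaries, mostly with low scores. Of the H3K4me3 summits 22172 (48.1%) lay over 2500 bp from every boundary, and 4986 did so among those with a score of at least 10. H3K27ac lay within 1000 bp of 56.2% (55.6 to 56.9) of the distal H3K4me3 summits and H3K4me1 of 52.2% (51.5 to 52.8). The 5 with the highest scores lay inside TPM3 on chromosome 1 at 154183062 (score 133), KRT8 on chromosome 12 at 52904517 (131), EIF3H on chromosome 8 at 116754694 (127), ZNG1F on chromosome 9 at 41188765 (126) and TXNRD1 on chromosome 12 at 104289516 (125). An H3K27ac summit lay within 1000 bp of the first 4 and 2327 bp from the last.

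Summit numbers differed between chromosomes, and to unlike degrees between the marks. Chromosome 13 held 920 H3K27ac and 596 H3K4me3 summits but 98 H3K4me1 summits, or 0.107 H3K4me1 summits per H3K27ac summit. On the other chromosomes analysed this ratio lay between 0.870 (chromosome 21) and 1.54 (chromosome 20). Of the 273 H3K27ac and 61 H3K4me1 summits left out, 74 and 44 lay on contigs and the rest on Y. Chromosome Y, which was not analysed, thus also held few H3K4me1 summits for its H3K27ac summits. H3K4me1 was within 1000 bp of 9.16% of the distal H3K27ac summits on chromosome 13, against 50.9% on X and 75.3% on chromosome 15, the lowest and highest of the others. On chromosome 13, 53.8% of 338 genes carried H3K4me3, within the range of 46.4% to 64.1% on the other chromosomes. Their median best H3K4me3 score was 24.2, against 41.0 on chromosome 22, the next lowest. The median best H3K27ac score was lowest on chromosome 13 too, at 13.1, against 23.2 on chromosome 14, the next lowest. Without chromosome 13 the genes with H3K4me3 and H3K27ac numbered 9317 of 19632, and 66.6% of the distal H3K27ac summits had H3K4me1.

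**Figure D5:**
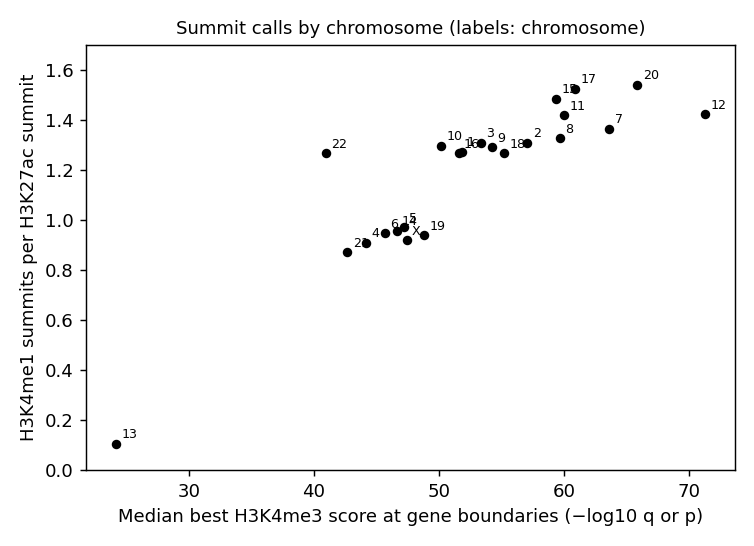
H3K4me1 summits per H3K27ac summit (y) against the median best H3K4me3 score at the boundaries of protein-coding genes (x, −log10 units), 1 point per chromosome. Chromosome 13 lies apart from the others drawn, at a ratio of 0.107 and a score of 24.2, and Y was left out.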

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

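Summits outside the assembled chromosomes, which enter no comparison of the report, numbered 74 for H3K27ac on 17 contigs, 44 for H3K4me1 on 14 contigs and 97 for H3K4me3 on 27 contigs. All 3 numbers exceed the 3 counts that a count of 0 allows. No test was made on them, and the input library was not analysed here.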

How the results depend on the processing

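Of 125 values compared with an alternative for the main results, 91 stayed within 1.5 times the value reported, the rest are given here, and their causes were not tested except that fewer summits remain under a stricter score or an equal length. Leaving out chromosome 13, the distal limits of 1000 and 5000 bp and merging within 500 bp moved none of them by over 1.5 times. A score of at least 10 left 30466 H3K27ac, 6801 H3K4me1 and 19923 H3K4me3 summits, and 225 genes with H3K4me1 at a boundary (219 summits at protein-coding boundaries). At that score 2212 distal H3K27ac summits had H3K4me1, 3290 distal H3K4me1 summits had no H3K27ac and 4986 H3K4me3 summits were distal. Co-located at that score were 2728 H3K27ac summits with H3K4me1 (52.8% before, then 8.95%) and 13423 with H3K4me3 (42.5%, then 44.1%). Of the H3K4me1 summits 2713 had H3K27ac (49.6%, then 39.9%) and 388 had H3K4me3 (22.1%, then 5.71%). Of the H3K4me3 summits 13155 had H3K27ac (61.5%, then 66.0%) and 367 had H3K4me1 (33.9%, then 1.84%). At that score 3 clusters held at least 10 summits and 7 genes at least 10 distal sites. Lists of equal length (46078 summits each) gave 1394 genes with H3K4me1, 13637 distal H3K27ac summits with H3K4me1, 21301 distal H3K4me1 summits without H3K27ac, 17126 H3K27ac summits with H3K4me1, 19259 H3K4me1 summits with H3K27ac, 11541 H3K4me1 summits with H3K4me3, and 107 clusters of at least 10 summits. A boundary window of 500 bp gave 1461 genes with H3K4me1 and 6220 with H3K4me3 and H3K27ac. At 2500 bp there were 4971 genes with H3K4me1 and 8793 H3K4me1 summits at boundaries, and with summits anywhere in the gene 8062 genes with H3K4me1. Co-location within 500 bp gave 28201 H3K4me1 summits with H3K27ac and 11170 with H3K4me3, and within 2000 bp 28731 with H3K4me3. Stitching within 5000 bp gave 216 clusters of at least 10 summits. Between 7 and 10 of the 26 gene lists lay above the central 95% of random lists and between 8 and 11 below it. This range covers the 2500 bp window, summits anywhere in the gene, a score of at least 10 and lists of equal length. The gene lists were not run with the 500 bp window. Among random lists matched on gene length 6 of the 25 lists of protein-coding genes lay above and 11 below, and among those matched on chromosome 6 and 10; the lncRNA list was not matched. The planned single start per gene, CpG matching and motif search were not run, because the gene table holds no strand, transcript or sequence. No paired analysis was possible because each mark had 1 library. Read depth of the libraries is unknown, so what it limits was not tested beyond the comparisons by chromosome given below.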

Other observations

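The gene classes in this paragraph and the test of hepatocyte genes with summits anywhere in the gene were chosen only after the result was seen. Genes of transfer RNAs, which RNA polymerase III transcribes, carried H3K4me3 within 1000 bp in 277 of 443 cases (62.5%, 57.9 to 66.9) and H3K4me1 in 3; neighbouring tRNA genes share windows. Of 18177 lncRNA genes 3975 carried H3K4me3 (21.9%, 21.3 to 22.5), and of 15212 pseudogenes 465 did (3.06%, 2.79 to 3.34), below the 3.53% of shifted lists. Genes of mitochondrial ribosomal proteins carried H3K4me3 with H3K27ac in 73 of 77 cases, against a median of 36 in random lists, and proteasome subunit genes in 34 of 40 against 19. Zinc finger genes with ZNF symbols carried it in 296 of 509 cases, against a median of 240, and protocadherin cluster genes in 1 of 53 against 25. Keratin genes had it in 6 of 55 against 26, serpin genes in 6 of 34 against 16, and cytochrome P450 genes, many of them active in hepatocytes, in 12 of 56 against 27. Genes of S100 calcium-binding proteins carried H3K4me1 at a boundary in 12 of 21 cases, against a median of 2, above all random lists. Neighbouring genes of a family can share a summit and were counted separately.

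Chromosome 13 held few H3K4me1 summits. A single long part missing from the list is argued against, since the widest gap between H3K4me1 summits, of 21.5 Mb, held 6.52% of the H3K27ac summits of the chromosome. Several missing parts would escape this test, and gene density was not tested. Fewer reads from chromosome 13, as fewer copies of it in these cells would give, may have put a mark with low scores under the calling threshold: its median best H3K4me3 score ranked 1 of the 23 chromosomes, lowest first. Over the other 22 chromosomes Spearman's rho of this score with the H3K4me1 to H3K27ac ratio was 0.879, but the ratios fell into 2 clusters, and within the 15 chromosomes with ratios from 1.27 to 1.54 rho was 0.821 (permutation p = 0.00029, Benjamini-Hochberg adjusted 0.000387 over 4 relations) and Pearson's r 0.70 (permutation p = 0.0022, adjusted 0.00293). Within the 7 chromosomes with ratios from 0.870 to 0.972 rho was 0.464 (exact permutation p = 0.30, adjusted 0.30) and r 0.71 (exact permutation p = 0.086, adjusted 0.086), chromosome 22 had a ratio of 1.27 at the next lowest score of 41.0, and copy number was not measured here. The 2 clusters were split on the ratio itself, and the 4 relations share chromosomes. With 1 library per mark, the p-values do not measure whether the relation would repeat.

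Few hepatocyte function genes carried H3K4me3 with H3K27ac. Promoters inside genes that boundary windows miss are argued against as the cause for most of these genes. H3K4me3 was found at a boundary in 11 of the 35 genes and anywhere in the gene in 13. The list stayed at percentile 0.030 of random lists with summits anywhere in the gene. Those random lists were not matched on gene length, so that percentile cannot decide by itself. Low read depth on the chromosomes of these genes is argued against too, since among random lists matched on chromosome the percentile was 0.040. Random lists were not matched on CpG content, so a part of CpG content in the low count stays open. The design holds no other cell type or condition, so no biological explanation was tested.

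Nearly as many H3K4me3 summits lay far from gene boundaries as near them. Of the distal H3K4me3 summits 65.4% lay inside a protein-coding gene, against 43.3% on average and 46.0% at most in 100 shifts. Transcription starts inside genes may account for part, but the gene table holds no such starts. All H3K4me1 summits were also in excess inside genes (57.3% against 41.9%), and H3K4me1 lay within 1000 bp of 52.2% of the distal H3K4me3 summits. The excess therefore cannot tell starts from enhancers inside genes. Weak calls near the score threshold stay open: 68.5% of the distal summits scored below the list's median, between the bounds set beforehand. H3K27ac lay within 1000 bp of 52.2% of these weaker summits and of 64.9% of the stronger ones.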
